A study of Nomascus leucogenys with 9 samples.

How the data were processed

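RNA-seq had been carried out on lymphoblastoid cell lines, which are B lymphocytes immortalised with Epstein-Barr virus (EBV) and grown in culture, from 9 northern white-cheeked gibbons (Nomascus leucogenys). Each line came from a different animal, per the series' design text, so the 9 libraries were taken as 9 biological replicates of 1 group. The labels' protocols state that total RNA was purified with an RNeasy Mini kit, that integrity was scored on a Bioanalyzer, and that libraries followed an Illumina TruSeq protocol. Neither poly(A) selection, strandedness, read length nor a library batch is given in the sources used here.

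The submitters' processing notes list Trimmomatic, STAR, edgeR and DESeq2, with no version, order or role. The genome build, the annotation and the exact normalization are not given in the sources used here. One table of the whole series was used, with 15356 rows and 1 column for each of the 9 lines. The values deposited by the authors were on a log scale and were treated as log2 expression. They held no 0 and no whole-number counts, and ran from 0.71 to 18.66. The base of the logarithm is not stated. Raised to base 2, the columns summed to between 13728358 and 14059842, which are called linear totals here, and levels in parts per 1000000 (ppm) refer to those sums. The near-equal totals show that the libraries had been put on a common scale before deposit, so the sequencing depth of each library is unknown and no counting interval or detection floor could be given. Of the 100 rows with the highest mean, 52.0% held values that were equal within 0.0001 in at least 1 pair of lines, against 2.25% of the other rows. Rows below 1 ppm had a median SD among the lines of 0.13, against 0.25 for rows of 1 to 10 ppm. The highest value was the same in 7 of the 9 lines. These features of the deposited log2 values are those of rank-based scaling and of a regularized log transformation, neither of which is stated in the sources used here. If either was used, every SD, range and fold given here is on that transformed scale, with differences in low rows reduced most, and can differ from the values in the unscaled counts.

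The header line of the table separated the last line names by a space in place of a tab. Split at white space it gave 1 name per field in every row, and columns were matched to samples by name. The number of per-sample columns left unused was 0.

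Row identifiers had the format of human Ensembl gene identifiers (15250 rows) or transcript identifiers (106 rows), although the animals are gibbons. Each printed row therefore carries the name of a human gene, and the human cell cycle lists could be matched by identifier. Whether reads were counted against a human reference, or gibbon genes were renamed after human ones, is not stated in the sources used here. The table did not pair the identifiers with gene symbols. The RefSeq gene table available here, for the assembly Asia_NLE_v1, holds 33914 genes and no Ensembl identifiers, and 0 of the 15356 identifiers matched. A total of 30 gene lists with 520 symbols, covering cell types, cell cycle, DNA repair, chromosome segregation, retroelement silencing, interferon response and antigen presentation, had been fixed before the data were examined. None of the 520 symbols could be matched, so the list comparisons, their correlations across lines and the chromosome-wide comparison were not made, and genes are given by identifier only. The rule for named genes, fixed at the same time, took the rows with the highest mean, the most variable rows past a threshold, and members of the lists. Without symbols and with 0 rows past the threshold, 4 rows are printed by identifier instead. They are the pair with the largest variance ratio among rows whose farthest line lay above the row median, and the pair among rows whose farthest line lay below it. That choice was made after their values were seen.

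Rows with a mean of at least 1 ppm of the linear total were kept, which left 12590 rows. No further pseudocount was added, because the values were already logarithmic. The planned model assumed linear values, and the deposited log2 values replaced the planned log2(value + 1). The spread of each row was described by its SD and its range over the lines. The variance of each row was tested with limma 3.58.1 in R 4.3.3, against a robust prior that follows the mean level, with Benjamini-Hochberg adjustment and a threshold of 0.05. The deviation of a line was its log2 value minus the median of the row over the lines. A line was called outlying in a row by Dixon's gap criterion for 9 values, which flagged 4.88% of rows in simulated normal data. Gene classes were set beside 10000 random lists of the same size, matched on mean level in 20 bins. Cell cycle lists keyed by Ensembl identifier were taken from the pair classifier shipped with scran 1.30.0, after the data had been seen.

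The variance test was tested on simulated data with 12590 rows in 9 lines. With a narrow simulated prior (20.0 degrees of freedom) it called 74.0% of rows whose SD was raised 3-fold and 100.0% of rows raised 5-fold. With the wide prior fitted to these data (2.75 degrees of freedom) it called 0 of 50 rows even at 20-fold. Alternatives covered the scaling of the libraries, the pseudocount, the filter, the form of the prior and the omission of each line. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.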

Results

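Gene expression was measured by RNA-seq in lymphoblastoid lines from 9 northern white-cheeked gibbons. The study concerned LAVA, a composite retrotransposon found in gibbons, and its use as regulatory sequence by the host genome. The labels gave no treatment and no contrast between animals, so the design supports a description of expression in 1 group and of how far the 9 lines differed. The lines were numbered in the order of their labels: 1 (Asia), 2 (Bobby), 3 (China), 4 (Khao), 5 (Melouprey), 6 (Nancy), 7 (Phyllis), 8 (Ricky) and 9 (Vok). LAVA insertions themselves were not analysed here. Animal, culture and EBV transformation event coincide in each line, so the design alone does not assign a difference between lines to any one of them.

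The share of the most abundant rows was similar in every line, but the authors' scaling had already brought the columns close together (7 of the 9 had the same maximum, 18.66 log2 units), so that similarity is not a measurement of the lines. The 10 highest rows of a line held between 9.12% (line 5) and 9.91% (line 1) of its linear total, and the 100 highest held between 22.7% (line 9) and 23.9% (line 8). The row with the highest mean reached 18.57 ± 0.18 log2 units (SD, n = 9), or 2.81% ± 0.31 of the linear total. The next row reached 18.01 ± 0.26 log2 units, or 1.92% ± 0.34. Mean levels were set in 3 classes, in parts per 1000000 (ppm) of the linear total. Of the 12590 rows kept, 3833 lay between 1 and 10 ppm, 6429 between 10 and 100 ppm and 2328 at or above 100 ppm. A further 2766 rows (18.0%) lay below the filter.

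The typical row differed little between lines, and a minority of rows differed by large factors. The median SD of a row over the 9 lines was 0.22 log2 units, with 90% of rows between 0.10 and 0.70. The median range from the lowest to the highest line was 0.68 log2 units, a 1.60-fold difference. In 3556 rows (28.2%) the range was under 0.5 log2 units. In 3327 rows (26.4%) the lines spanned at least 2-fold, in 778 rows (6.18%) at least 4-fold and in 54 rows at least 16-fold. Among the kept rows, wide ranges were more frequent at low levels. A range of at least 4-fold was found in 8.77% of rows at 1 to 10 ppm, in 5.94% at 10 to 100 ppm and in 2.58% at or above 100 ppm. Below the filter the share was 0.36%. Without line 1 the number of rows spanning at least 4-fold was 517.

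**Figure D1:**
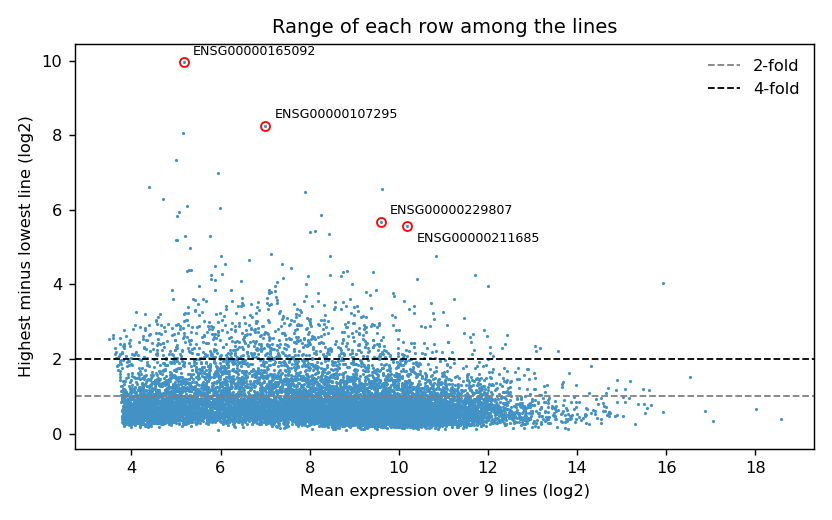
Range of each kept row among the lines (highest minus lowest line, log2 units) against its mean over the 9 lines (log2 units), 1 point per row. Dashed lines mark 2-fold and 4-fold ranges, which 3327 and 778 of the 12590 rows reached, and red circles mark the 4 rows printed by identifier.

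No single row stood out against the spread of its peers in the formal test. limma's variance test with Benjamini-Hochberg adjustment called 0 of 12590 rows, with a smallest adjusted p of 0.904. At an unadjusted p under 0.05 it listed 658 rows, or 5.23%. The prior was fitted to the variances of these same rows, so a share near the threshold is built in and is not a finding. Variances differed so much from row to row (prior of 2.75 degrees of freedom) that the test had no power in simulated data of this kind, and the count of 0 does not show that rows were alike. No other tool was run.

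Of the rows with large variance ratios, 4 were therefore described by their values, under the human-format identifiers of the table, and other rows had wider ranges than some of these. ENSG00000165092 was high in 1 line. Its level was 13.44 log2 units in line 1, 6.42 in line 6 and between 3.49 and 4.41 in the other lines (mean 5.18 ± 3.23, SD, n = 9). ENSG00000107295 had its highest level in the same line, at 13.09 log2 units. It followed at 9.52 in line 3 and 8.10 in line 6, and lay between 4.84 and 6.56 elsewhere (mean 7.003 ± 2.80, SD, n = 9). Their full ranges were 993-fold and 306-fold. Each had a limma adjusted p of 0.904.

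ENSG00000229807 split the lines into separate levels. It reached 11.73 log2 units in line 1, 12.15 in line 3, 12.32 in line 6, 11.43 in line 7 and 11.97 in line 8. It stood at 6.68 in line 2, 6.70 in line 4, 6.76 in line 5 and 6.63 in line 9. The gap between the levels was 4.67 log2 units, or 25.5-fold, and no line lay inside it (mean 9.60 ± 2.77, SD, n = 9). The gene named by this identifier was not looked up, and what separates the groups of lines was not tested. ENSG00000211685 was graded instead. It ran from 7.31 log2 units in line 6 and 7.52 in line 1 through 9.07 in line 5, 9.93 in line 3, 10.40 in line 4 and 10.54 in line 8. The highest values were 12.03 in line 7, 12.05 in line 9 and 12.89 in line 2 (mean 10.19 ± 1.97, SD, n = 9). Both rows had a limma adjusted p of 0.904.

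**Figure D2:**
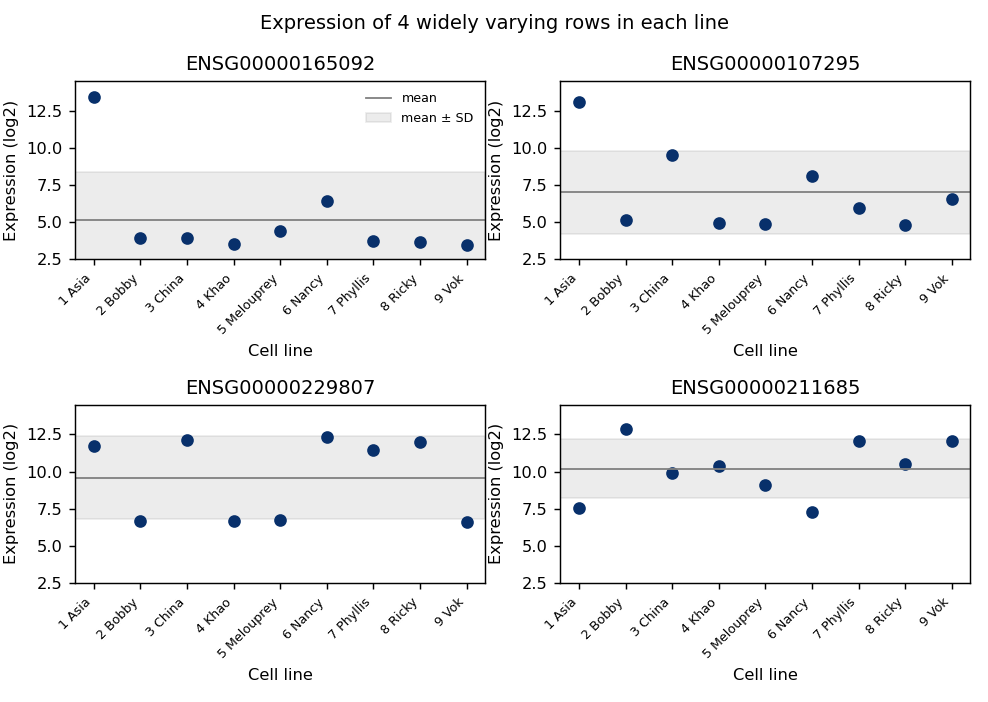
Expression (log2 units) of 4 widely varying rows in each of the 9 lines, 1 point per line, with the mean as a line and the mean ± SD as a band. ENSG00000165092 is high in line 1 alone, while ENSG00000229807 takes 5 values at or above 11.43 and 4 values at or below 6.76.

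The lines were similar in their overall profiles, and lines 1, 3, 6 and 9 departed most from the others. Pearson correlations across the 12590 rows, which are not independent replicates, ranged from 0.960 (lines 1 and 4) to 0.994 (lines 2 and 8). No library was a copy of another, since at most 23 of the 12590 rows were equal within 0.0001 in any pair. The smallest SD of the difference between a pair was 0.27 log2 units, for lines 2 and 8. The mean correlation with the other lines was lowest in line 1, at 0.965, and highest in line 8, at 0.983. The SD of a line's deviations from the row medians was 0.53 log2 units in line 1, 0.42 in line 6, 0.40 in line 9 and 0.39 in line 3. It lay between 0.22 and 0.32 in the other lines. Among rows at or above 100 ppm, line 9 (0.41) and line 1 (0.41) were alike, and the others lay between 0.16 and 0.29.

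**Figure D3:**
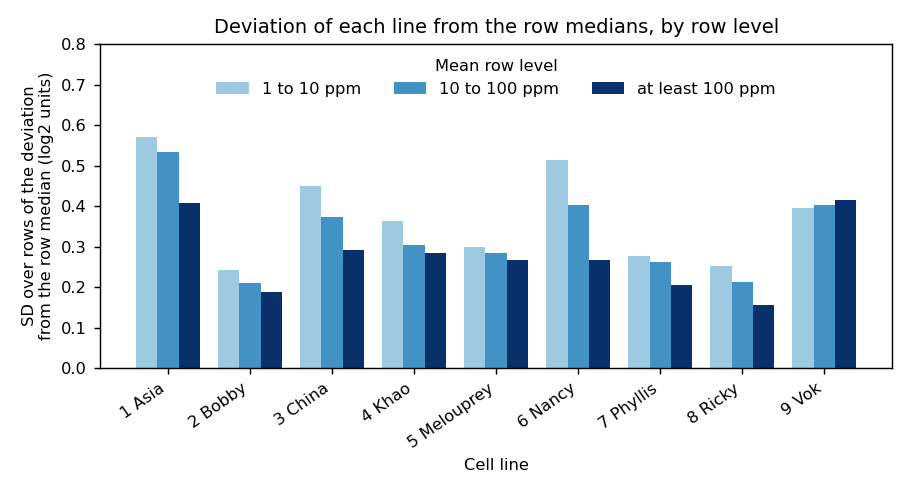
SD over rows of each line's deviation from the row median (log2 units), for rows of 3 mean levels, 1 bar per line and level. Line 1 has the highest bar in rows of 1 to 10 ppm (0.57), and lines 1 and 9 share the highest bars (0.41) in rows at or above 100 ppm.

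Line 1 was at least 2-fold above the row median in 428 rows and at least 2-fold below it in 331 rows. Line 6 was above in 311 rows and below in 121, and line 3 above in 259 and below in 152. Line 9 was above in 146 rows and below in 162. Line 2 had 35 such rows in each direction. A single outlying line was found by Dixon's criterion in 1268 rows (10.1%), against 4.88% in simulated normal data. The outlying line was the highest in 819 rows and the lowest in 449. Line 1 was the outlying high line in 362 rows and line 9 in 242. In the other direction the order was reversed, with line 9 the outlying low line in 191 rows and line 1 in 130.

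In a principal component analysis, the first component held 34.2% of the variance. Line 1 scored 47.96 on it, line 6 scored 20.18 and line 3 scored 18.76, while the other lines scored between -20.93 and -9.93. The second component, with 19.1%, had line 9 at 35.12 and line 6 at -22.64 as its ends. With line 1 left out, the first component held 30.7%.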

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

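The tests on the deviation of line 1 were fixed before their outcomes were seen, and the test of rows shared by lines 1 and 6 was chosen after the pattern was seen. Of 20 sets of 9 values that were checked for an outlying line, 4 gave one. Chance flags about 1 in 20 independent sets, but that rate does not apply as it stands, because 12 of these sets are overlapping summaries of the same lines and 4 are rows picked for their spread.

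ENSG00000165092 was flagged because its level of 13.44 log2 units in line 1 lay far above the other lines, of which the nearest was 6.42, although the row had been picked for its spread. Line 1 was also apart in the number of rows at least 2-fold below the row median, 331 against 162 in the next line. Line 9 had the smallest share of its linear total in its 100 highest rows, 22.7%, and the smallest linear total, 13728358.

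Line 1 deviated from the row medians with an SD that was 1.77 times the median of the other lines (95% bootstrap interval over rows 1.68 to 1.87, which covers the choice of rows only). It had the largest SD of all lines in these same values, so a ratio above 1 was built in. The tests asked whether the ratio stayed above 1.2, a bound that line 6 (1.39), line 9 (1.33) and line 3 (1.27) passed too over all kept rows. Sampling noise in a shallow library would fade in abundant rows. At or above 100 ppm of the linear total the ratio was 1.53 (1.42 to 1.71), although line 9 equalled line 1 there. Counting noise falls with level in every library and the depths are unknown, so a ratio between lines cannot exclude it. An offset of the library that depends on level was removed with a smooth trend, and the ratio was 1.73 (1.63 to 1.82). A few extreme rows are not enough either, because the ratio of median absolute deviations was 1.46 (1.43 to 1.51), though line 9 exceeded line 1 on that measure (0.21 against 0.19). What stays open is sampling noise, a difference between the animals, the cultures or their EBV clones, a library batch, or cells of another type. RNA integrity and the alignment reference stay open too, and the table and labels separate none of these. Line 1 is named Asia, as is the assembly Asia_NLE_v1. Whether that assembly is of the same animal, or was used for these reads, is not known here.

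Among the 778 rows that spanned at least 4-fold, the largest gap set lines 1 and 6 above all others in 38 rows, lines 1 and 3 in 27 rows and lines 1, 3 and 6 in 19 rows. Shuffling that kept each line's own spread but broke the link between lines gave at most 14 rows for lines 1 and 6 in 200 shuffles. The shuffles also mixed rows of wide and narrow spread, and they counted only this pair, the one with the most rows. They therefore cannot exclude that lines 1 and 6 vary independently in rows of wide spread. Shared genetics, a shared state of the B cells and a shared handling of these libraries remain open, since no label places the lines together. No biological explanation was tested.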

How the results depend on the processing

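The settings tried for the variance test were fixed before the data were examined, apart from a pseudocount of 1 on the linear scale, and all settings for the other results were added afterwards. limma's variance test gave 0 rows under every scaling, pseudocount, filter, prior and omission of a line that was run, with 503 to 844 rows at an unadjusted p under 0.05. Because the test had no power at this spread of variances, and its prior was fitted to the same rows, neither count says anything about stability. The number of rows spanning at least 2-fold lay between 2469 and 3521 under the other settings and between 2772 and 3293 when a line was left out. The number spanning at least 4-fold lay between 587 and 798, and between 517 and 766 when a line was left out. The value of 517, without line 1, was the only one to differ from 778 by more than 1.5 times, since that line is an end of many of these ranges. The share of rows with an outlying line lay between 9.36% and 12.2%, or between 8.37% and 11.1% with a line left out. The ratio of line 1 to the median of the other lines lay between 1.76 and 1.80, or between 1.58 and 2.06 with another line left out. The variance ratio of ENSG00000165092 was 190.1 as deposited, 26.9 without line 1, 69.4 with a filter of 5 ppm of the linear total and 252.2 with a prior without trend. That of ENSG00000107295 was 126.3 as deposited, 52.1 without line 1 and 190.2 with a prior without trend. That of ENSG00000229807 was 229.2 as deposited, where it ranked first among kept rows, but 185.4 with a prior without trend and 216.2 without line 6, below ENSG00000165092 (226.5 without line 6) in both. The causes of the changes with filter and prior were not tested. No rescaling moved the median of all rows by more than 0.1 log2 units. The mean pairwise correlation of the cell cycle lists, which are keyed by identifier, lay between 0.13 and 0.17 for S-phase genes, 0.070 and 0.11 for G2M genes and 0.032 and 0.070 for G1 genes over all settings. The correlations between list levels stayed positive in all of them, with adjusted exact permutation p under 0.05 except for G1 and G2M without line 9 (r = 0.68, adjusted p = 0.060, n = 8). The other settings for the gene lists defined by symbol and for chromosomes were not run, because no identifier could be matched to a symbol or position. No paired analysis was possible because there is 1 group. Depth is unknown, so the part of the spread that comes from counting in low rows could not be removed.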

Other observations

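The tests of single cell cycle lists were fixed before their outcomes were seen, and the correlations between lists were chosen after the levels of the lists were seen. Genes of the cell cycle varied together among the lines, though by small amounts. The lists are identifiers that a classifier trained on human embryonic stem cells uses as the higher member of at least 90% of its pairs for 1 phase, over at least 20 pairs. The table held 180 of 206 S-phase identifiers, 172 of 178 G2M identifiers and 197 of 220 G1 identifiers, of which 176, 169 and 193 passed the filter. S-phase genes were highest in line 5, by 0.15 log2 units on average above their row medians, followed by 0.13 in line 9 and 0.12 in line 7. They were lowest in line 4, at -0.13, line 6, at -0.10, and line 1, at -0.09, a 1.22-fold span. G2M genes were highest in line 9, at 0.17, and lowest in line 4, at -0.09. G1 genes ran from -0.09 in line 1 to 0.09 in line 9. A range of at least 4-fold was found in 7 genes of each list.

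The mean pairwise correlation across lines was 0.15 among S-phase genes, 0.086 among G2M genes and 0.042 among G1 genes. Lists matched on level gave 95% of values between -0.0039 and 0.013, between -0.0040 and 0.015, and between -0.0035 and 0.015. Structure shared by rows of the same level therefore does not account for any of the 3 values. The lists were not matched on SD, which was high for S-phase and G2M genes. For those genes, structure shared by widely varying rows is not excluded. The median SD of S-phase genes (0.24) lay above 99.99% of the matched lists, that of G2M genes (0.23) above 97.4% and that of G1 genes (0.21) above 56.5%.

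One hypothesis is that the lines differ in how many cells are cycling. Over the 9 lines, S and G2M levels correlated with r = 0.82 (exact permutation p = 0.0079, adjusted 0.012; rho = 0.83, p = 0.0083, adjusted 0.0083; 3 relations computed, shared genes left out). Without lines 5 and 9, the farthest from the median, r was 0.86. Lists matched on level in place of G2M gave a median r of 0.14, and 95% of them gave values between -0.76 and 0.82, so the observed r lay at the edge of what such lists give (97.5 percentile). G1 and S levels correlated too, with r = 0.88 (exact permutation p = 0.0019, adjusted 0.0056; rho = 0.87, p = 0.0045, adjusted 0.0083; r = 0.95 without lines 1 and 9), at the 98.5 percentile of matched lists. For G1 and G2M, r was 0.79 (exact permutation p = 0.012, adjusted 0.012; rho = 0.83, p = 0.0083, adjusted 0.0083; r = 0.78 without lines 1 and 9), at the 94.6 percentile of matched lists, and without line 9 it was 0.68 (exact permutation, adjusted p = 0.060). The hypothesis stays open, since the S and G2M correlation lies inside the central 95% of matched lists. That bound was chosen after the values were seen, and a one-sided bound at the 95th percentile, used first, would have put it above. The number of cycling cells does not fix the sign of a correlation with G1 genes, so the G1 values are given without an explanation.

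ENSG00000229807 was the only one of the 778 rows with a range of at least 4-fold whose largest gap set lines 1, 3, 6, 7 and 8 above the rest. The same division in the opposite direction, with lines 2, 4, 5 and 9 above the rest, was found in 1 row. The 65 kept rows named by a transcript identifier had a median SD of 0.22, at the 26.3 percentile of matched lists, and a mean pairwise correlation of 0.042, at the 52.1 percentile.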
